A study of Homo sapiens with 18 samples.

How the data were processed

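RNA from cells labelled HepG2 was measured on 18 single-channel Illumina bead arrays, 3 in each of 6 groups given by siRNA (scramble, si-PSTAR, si-hnRNP K) and doxorubicin (none, or 400 nM for 16 hours). Per the labels' protocols, total RNA was extracted, amplified with an Illumina RNA amplification kit and hybridised. The labels' treatment protocol gives more than 1 exposure time, and the series' design text gives 16 hours for these arrays, which was used. The series' text describes drug treatment for each transfection, while the sample labels also give untreated arrays; the sample labels were followed.

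The deposited table holds log2 intensities of 43961 probes. That the values are log2, and that they had been quantile normalized by the authors before deposit, was read from the values: at 99.9955% of ranks the 18 sorted columns differed by under 0.01, and the medians were equal. The software and the background correction are not given in the sources used here. No detection p-values were used. The values were used as deposited, with no further scaling.

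Probes were named through the supplied probe table, with symbols brought to the current ones by gene identifier in the RefSeq gene table of GRCh38.p14. Of the probes, 29511 had 1 gene symbol, 0 had several and 14450 had none here; 29474 matched by identifier and 0 symbols changed. No coordinates are given because the array files name no genome build. Each of 19782 genes took its probe with the highest mean over all arrays; 6483 genes had more than 1 probe. Genes whose mean was below the median of all probes, 5.72, were left out, which removed 7299 and left 12483.

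A linear model with 6 group means was fitted to all arrays with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation on 12 residual and 13.5 prior degrees of freedom. The 7 two-group comparisons and 2 interactions were tested two-sided with Benjamini-Hochberg adjustment within each, at 0.05. The direct contrasts between arrays labelled si-hnRNP K and si-PSTAR were fitted in the same model. For 22 gene lists with 513 different genes, camera was run with a preset correlation of 0.01, adjusted over lists within a comparison; an estimated correlation and fry, which tests whether a list's genes move on balance one way without comparing them with other genes, were alternatives. Exact permutation of 3 arrays against 3 cannot give a p below 0.1, so single genes rest on the model.

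The genes named were HNRNPK, MDM2, CDKN1A and MYC in each two-group comparison (a further gene of the rule is not analysed here), the 10 largest rises and 10 largest falls among called genes of which all 3 arrays of one group lay above those of the other, up to 4 members with the smallest p of each list mentioned, and the 5 largest interactions each way. SD, SE and n refer to arrays. The lists, the design, the naming rule and the alternatives were fixed before the data were examined. The comparison of probes within genes, the clusters of arrays and a fit of 12 arrays were chosen after seeing the data. For the clusters, arrays were joined by average linkage on 1 minus Pearson's r, and bootstrap intervals used 1000 draws over genes.

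The similarity of the differences of both labelled siRNA groups from scramble was set against 100 simulations of unchanged groups with shared controls. The size of the DOX response was a slope through the origin, with an error from leaving out 1 array at a time. The fits were tested on simulated data with the real means and spreads of 12483 genes: for si-PSTAR with DOX, with 200 genes changed, 99 of 100 changed by 1 log2 unit and 73 of 100 changed by 0.5 were called, with 9 false calls among 181.

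Alternatives were cyclic loess, centring on the 75th percentile, no filter or a filter at the 70th percentile, the mean of a gene's probes, a fit of the compared arrays alone, a replicate block, a trended robust prior, array weights and leaving out each array. Figures were drawn with matplotlib 3.10.9.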

Results

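Gene expression was measured in cells labelled HepG2, a line derived from a human liver carcinoma, after transfection with a scramble control siRNA, an siRNA against PSTAR (a long noncoding RNA) or an siRNA against hnRNP K (an RNA-binding protein encoded by HNRNPK). Each siRNA was studied without and with 400 nM doxorubicin (DOX), a DNA-damaging drug, for 16 hours. The 6 groups held 3 arrays each, 18 Illumina bead arrays in all, and 12483 genes were tested. All arrays had the same distribution of values, with a median of 5.73 log2 units. The number of arrays limits the precision. Nothing in the labels says that the 3 arrays of a group came from separate cultures, so the p-values measure the spread between these arrays, which may be technical.

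The first comparison asked whether the hnRNP K siRNA lowered its target, and HNRNPK ran against the labels. On its brightest probe, HNRNPK stood at 11.72 ± 0.09 log2 units (SD, n = 3) in untreated scramble arrays and at 11.95 ± 0.07 with DOX. In the arrays labelled si-PSTAR it stood at 8.44 ± 0.02 without DOX and at 8.32 ± 0.14 with DOX, 9.74-fold and 12.4-fold lower than scramble (limma adjusted p = 2.34e-19 and 2.89e-19). In the arrays labelled si-hnRNP K it stood at 11.55 ± 0.12 and 11.36 ± 0.22. Those arrays differed from scramble by -0.17 log2 units without DOX (adjusted p = 0.222) and by -0.59 with DOX (adjusted p = 5.13e-05). The probes with means of 10.26 and 7.78 fell by 2.61 and fell by 2.42 on the log2 scale in DOX-treated arrays labelled si-PSTAR, and differed by 0.027 and -0.20 in those labelled si-hnRNP K (adjusted p over all probes = 0.922 and 0.197). The dimmest of the 4 probes, with a mean of 6.39, differed by 0.10 and -0.11. Without DOX these 3 probes changed by -3.71, -2.37 and -0.48 in arrays labelled si-PSTAR. The probe with a mean of 10.26 changed by -1.17 with DOX in scramble and by -0.91 with DOX in arrays labelled si-hnRNP K. No named probe measured PSTAR. All directions below therefore hold for arrays as labelled.

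**Figure D1:**
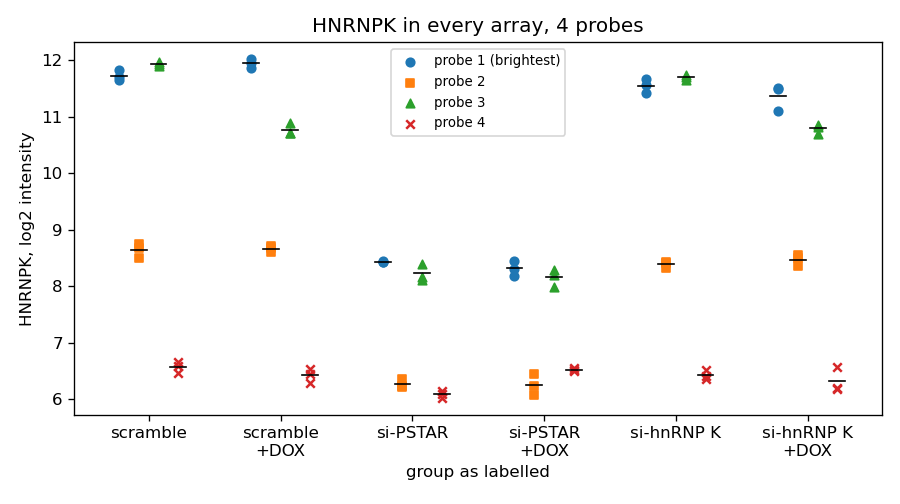
HNRNPK intensity on a log2 scale (vertical axis) in each of the 18 arrays, by labelled group (horizontal axis), for the 4 HNRNPK probes; each point is an array and each black line a group mean. The brightest probe lies near 8.44 and 8.32 in the arrays labelled si-PSTAR and between 11.36 and 11.95 in the means of the other groups.

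The arrays also fell into 2 clusters that followed neither the siRNA alone nor the drug alone. Untreated scramble and untreated si-hnRNP K arrays, 6 in all, formed one cluster and the other 12 arrays formed another. Every DOX-treated array and every array labelled si-PSTAR lay in the larger cluster, so the clusters are not independent of drug or siRNA label. The correlation across genes between arrays was at least 0.978 within the smaller cluster, at least 0.957 within the larger and at most 0.963 between them. For 1169 genes with at least 2 probes above 7.5 log2 units, the log2 changes on the 2 brightest probes were compared, across genes, which are not independent replicates. The correlation between probes was 0.862 for si-hnRNP K without DOX, 0.776 for si-PSTAR with DOX, 0.760 for si-hnRNP K with DOX and 0.558 for DOX in si-PSTAR, all of which lie within 1 cluster. It was 0.296 for si-PSTAR without DOX, 0.230 for DOX in scramble and 0.229 for DOX in si-hnRNP K, which set arrays of both clusters against each other. The 4 comparisons within a cluster are given first.

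**Figure D2:**
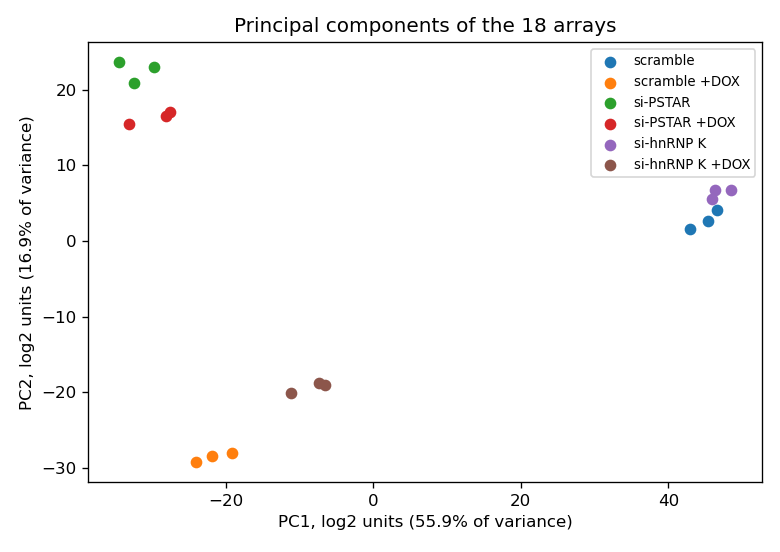
First principal component (horizontal axis, 55.9% of the variance) against the second (vertical axis, 16.9%) of the log2 values of all tested genes, 1 point per array, coloured by labelled group. The untreated scramble and untreated si-hnRNP K arrays lie together, apart from the other 12 arrays.

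**Figure D3:**
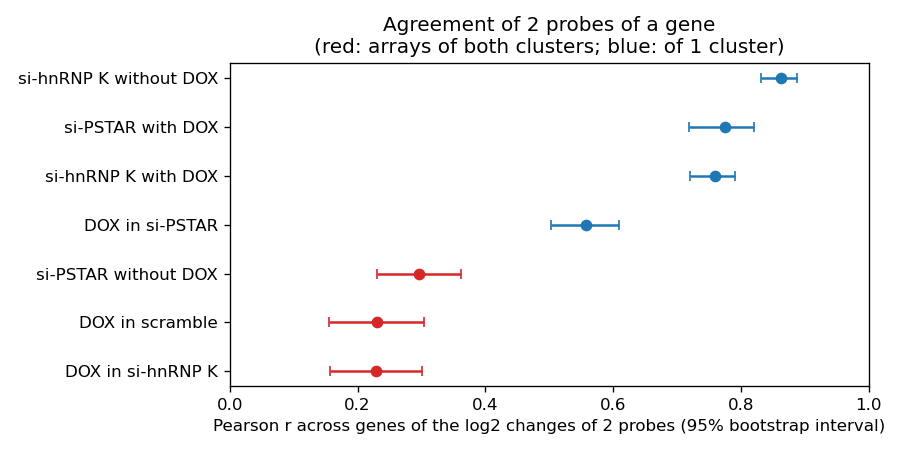
Pearson correlation (horizontal axis) across 1169 genes between the log2 changes of the 2 brightest probes of a gene, for each two-group comparison (vertical axis), with 95% bootstrap intervals over genes as bars. Comparisons within 1 cluster of arrays lie between 0.558 and 0.862, and those between clusters between 0.229 and 0.296.

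The series asks how expression changes after PSTAR or hnRNP K knockdown, and its design text describes cells given DOX. With DOX, arrays labelled si-PSTAR had lower levels of p53 target genes than scramble arrays. Of 20 tested targets of arrest, repair and feedback, 14 fell and 0 rose over all genes tested, and 14 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.65e-07). XPC, a DNA damage sensor of nucleotide excision repair, was 7.04-fold lower, GDF15, a secreted stress cytokine, 6.34-fold lower, CDKN1A, which encodes the cell cycle inhibitor p21, 5.67-fold lower, and SESN1 fell by 1.92 ± 0.09 log2 units (SE). CDKN1A went from 14.31 in scramble to 11.80, and its second bright probe differed by -0.47. MDM2, the p53 ubiquitin ligase, differed by -0.07 (adjusted p = 0.606). The MDM2 probe was weak in every group, not far above the median of all probes. Its group means ran from 5.86 (si-hnRNP K with DOX) to 6.46 (scramble with DOX). MDM2 differences, here and below, may therefore be limited by background, and a small one does not show that MDM2 was unchanged. Among 17 targets linked to cell death, 8 fell and 2 rose, or 9 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.123). TP53I3 fell by 2.14, BAX by 1.34 and AEN by 1.15, and CASP1 rose by 0.91.

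In the same comparison, genes of ribosome biogenesis rose, 18 of 26 higher and 2 lower (18 and 3 adjusted over the list alone, camera adjusted p = 0.000118). NOLC1 rose by 1.64, NOP56 by 1.01 and PPAN by 0.96. Genes of the amino acid stress response rose, 16 of 20 higher and 1 lower (17 and 1 adjusted over the list alone, adjusted p = 3.64e-07, and adjusted p = 0.0552 with an estimated correlation), among them ATF4 by 1.43, ASNS by 1.36, TRIB3 by 1.28 and PHGDH by 1.22. Cholesterol synthesis genes fell, 11 of 17 lower and 0 higher (12 and 0 adjusted over the list alone, adjusted p = 0.0082), with INSIG1 changed by -1.09, NSDHL by -0.87 and MVK by -0.54. Immediate early genes fell, 13 of 21 lower and 2 higher (the same counts adjusted over the list alone, adjusted p = 0.00261, and adjusted p = 0.0682 with an estimated correlation), with CCN1 changed by -1.76, SRF by -1.23 and EGR1 by -0.94. Interferon response genes went both ways, 11 of 23 lower and 5 higher by either adjustment (adjusted p = 0.0082, and adjusted p = 0.202 with an estimated correlation), and ISG15, IFIT1 and IFIT2 changed by -1.91, -1.86 and -1.84.

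The largest rises were those of SOD2, the mitochondrial superoxide dismutase, 6.65-fold, SMDT1 5.11-fold, SNORD13 4.69-fold, TEX19 4.63-fold, VAMP1 4.14-fold, INHBE 4.11-fold, PRG4 3.82-fold, the metallothionein gene MT1F 3.81-fold and C1S 3.58-fold. TSPY26P also ranked among them, at 8.02 against a dim level of 5.52 in scramble. Dim means a mean below the median of all probes, 5.72, which is no measure of background. No fold between groups is given against such a level here or below. Folds against levels just above it, such as 5.95 for INHBE in scramble, may be limited by background too. Besides HNRNPK and the p53 targets above, the largest falls were those of PLAAT4 at 7.97-fold, DYNLT2B at 7.33-fold, PC, the gene of pyruvate carboxylase, at 7.23-fold, ALPK2 at 6.45-fold, LIAT1 at 6.01-fold and DCAKD at 5.78-fold. Of 3 PC probes, 1 changed the other way, by 0.53. MYC was higher by 0.48 (adjusted p = 0.000126). In all, 5618 genes changed, 2792 higher and 2826 lower, and 532 changed at least 2-fold. The 3 arrays of one group lay entirely above those of the other for 52.4% of genes, where chance gives 10% if the arrays of both groups are exchangeable. Repeats of the same culture would not be, so this share is no test of the siRNA.

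**Figure D4:**
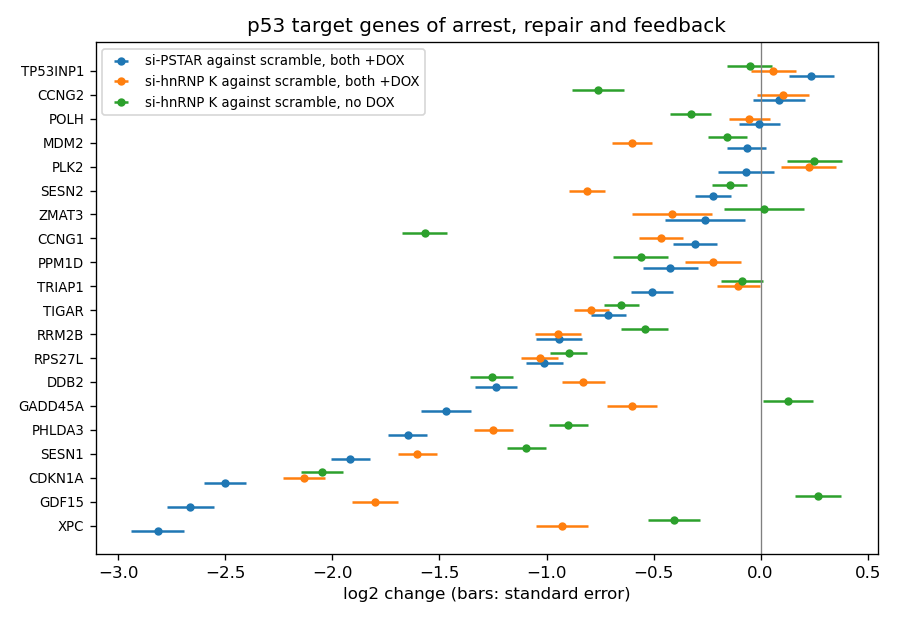
Log2 change (horizontal axis) of each of 20 tested p53 targets of arrest, repair and feedback (vertical axis) in 3 comparisons within a cluster of arrays, with standard errors as bars. CDKN1A was lower in each, by 2.50, 2.13 and 2.05 log2 units, and GDF15 was lower by 2.66 and 1.80 with DOX but differed by 0.27 without it.

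Arrays labelled si-hnRNP K and treated with DOX also had lower p53 targets than scramble with DOX. Of the 20 targets of arrest, repair and feedback, 13 fell and 0 rose by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 3.51e-08). CDKN1A was 4.39-fold lower, and SESN1, GDF15, PHLDA3 and MDM2 changed by -1.60, -1.80, -1.25 and -0.60 log2 units. The second CDKN1A probe differed the other way, by 0.38. The cell death targets did not pass as a list (adjusted p = 0.104), with 7 lower and 2 higher, or 8 and 2 adjusted over the list alone, and had an adjusted p of 0.0432 without DOX-treated scramble replicate 2. Interferon response genes fell, 17 of 23 lower and 1 higher (18 and 1 adjusted over the list alone, adjusted p = 1.94e-10), with IFIT2 6.54-fold, ISG15 4.84-fold and OASL 4.32-fold lower and IFITM1 changed by -1.86, while the second OASL probe differed by -0.995. Histone genes rose, 12 of 15 higher and 1 lower by either adjustment (adjusted p = 1.49e-07), H2BC5 by 1.89, H2AC6 by 1.44, H4C8 by 1.31 and H2BC8 by 1.10.

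Small noncoding RNA genes held most of the largest rises there. SNORD3A, SNORD3C and SNORD3D, which encode the U3 RNA of ribosomal RNA processing, were 14.2-fold, 12.5-fold and 13.1-fold higher, and the spliceosomal RNA genes RNU4-2, RNVU1-18, RNU1-3 and RNVU1-7 were 13.2-fold, 13.0-fold, 12.2-fold and 11.6-fold higher. These RNAs belong to families of near-identical copies, which 1 probe may not tell apart. Which forms of these RNAs and of the histone RNAs were amplified was not tested, here or without DOX. The values are therefore probe intensities and may not follow total RNA levels. CGA rose by 3.59 on the log2 scale, SNORA12 was 7.28-fold higher, and SCG2 stood at 8.61 against a dim level of 5.70. Further large falls were those of PLAAT4 at 7.18-fold, C1QTNF1 at 5.84-fold, AHNAK2 at 4.47-fold, CD70 at 4.33-fold, GRB7 at 4.25-fold and TACC1 at 4.19-fold. Other C1QTNF1 probes differed by -0.72 and -0.16. Markers of the epithelial to mesenchymal transition fell, 8 of 11 lower and 0 higher (8 and 1 adjusted over the list alone, adjusted p = 0.000526), with ACTA2 changed by -1.22 and PLAUR by -1.10. Ribosome biogenesis genes rose, 14 of 26 higher and 0 lower (16 and 0 adjusted over the list alone, adjusted p = 3.81e-05), among them NIP7 by 0.98 and RRP12 by 0.93. The amino acid stress list passed at an adjusted p of 0.0239 (adjusted p = 0.294 with an estimated correlation), 11 of 20 higher and 4 lower (12 and 4 adjusted over the list alone), and ATF4 was 2.83-fold higher. Long noncoding RNA genes passed at an adjusted p of 0.0239 as well (adjusted p = 0.0531 with an estimated correlation), 7 of 14 higher and 1 lower (8 and 1 adjusted over the list alone), with HULC higher from a dim level of 5.46. MYC was higher by 0.58. In all, 4960 genes changed, 2473 higher and 2487 lower, 397 of them at least 2-fold.

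Without DOX, arrays labelled si-hnRNP K had higher histone genes and lower interferon response genes and p53 targets of arrest, repair and feedback than untreated scramble arrays. Among the largest rises, the small RNA genes RNU1-3, RNVU1-7, RNVU1-18, RNU4-2, SNORD3D, SNORD3A, RNU1-1 and SNORD3C were 16.9-fold, 16.2-fold, 16.2-fold, 12.7-fold, 12.6-fold, 12.2-fold, 10.1-fold and 8.97-fold higher, CGA was 13.3-fold higher, and SCG2 stood at 8.60 against a dim level of 5.62. Interferon response genes fell, 15 of 23 lower and 1 higher (16 and 2 adjusted over the list alone, adjusted p = 6.71e-08), IFIT2 5.21-fold. Histone genes rose, 13 of 15 higher and 1 lower by either adjustment (adjusted p = 4.82e-07), H2BC5 by 1.32. Of the p53 targets of arrest, repair and feedback 12 of 20 fell and 0 rose (12 and 1 adjusted over the list alone, adjusted p = 1.78e-06). CDKN1A was 4.14-fold lower, CCNG1 changed by -1.57, DDB2 by -1.26 and SESN1 by -1.09. GDF15, named here after its values were seen, differed by 0.27 (adjusted p = 0.0594). The second CDKN1A probe differed the other way, by 1.16. MDM2 differed by -0.16 (adjusted p = 0.217) and MYC was higher by 0.62. The cell death targets did not pass (adjusted p = 0.452), with 4 higher and 4 lower, or 4 and 5 adjusted over the list alone.

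Other lists that passed in this comparison were ribosome biogenesis, 12 of 26 higher and 1 lower (14 and 1 adjusted over the list alone, adjusted p = 0.000284), and the amino acid stress response, 13 of 20 higher and 4 lower (14 and 4 adjusted over the list alone, adjusted p = 0.000108, and adjusted p = 0.0883 with an estimated correlation). Cholesterol synthesis passed with 10 of 17 lower and 1 higher (11 and 1 adjusted over the list alone, adjusted p = 0.000969). Markers of the epithelial to mesenchymal transition, a list that also names the epithelial genes CDH1 and EPCAM, passed with 8 of 11 lower (9 adjusted over the list alone, adjusted p = 0.000158). With the same counts adjusted over the list alone, so did mitosis, 14 of 29 lower and 1 higher (adjusted p = 0.00437), and long noncoding RNA genes, 8 of 14 higher and 1 lower (adjusted p = 0.00663). ASNS rose by 1.33 and SNHG12 by 0.85, while MSMO1 changed by -0.89 and TOP2A by -0.64. Further large falls were those of C1QTNF1 at 5.35-fold, MAPRE1 at 5.15-fold, PLAAT4 at 4.35-fold, AHNAK2 at 4.31-fold, TACC1 at 4.01-fold, HLA-B at 3.85-fold and NCEH1 at 3.83-fold, and ARL6IP5 changed by -1.93. Other TACC1 probes differed by -0.47 and -0.41, and other C1QTNF1 probes by -0.62 and -0.14. In all, 4153 genes changed, 2126 higher and 2027 lower, 345 of them at least 2-fold.

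Set side by side under DOX, the differences of arrays labelled si-PSTAR and of arrays labelled si-hnRNP K from scramble correlated at 0.449 ± 0.012 across genes (jackknife SE). Both comparisons share the scramble arrays with DOX, and simulated unchanged groups gave a correlation of 0.499 from that sharing alone. The covariance was 0.0871 against 0.0057 in the simulations, a difference of 0.0814. Of the calls, 1243 genes were higher in both and 1287 lower in both, where independent lists would share 553.12 and 563.03, and 544 of the 3074 genes called in both went opposite ways. With 3 controls no split into parts of at least 2 arrays was possible, so part of the excess may come from the shared controls. Tested directly, 5402 genes differed between the arrays labelled si-hnRNP K and si-PSTAR under DOX, 2787 higher and 2615 lower in the former. Histone genes were higher in the former, 12 of 15 (14 adjusted over the list alone, camera adjusted p = 4.47e-06). The p53 targets of arrest, repair and feedback did not pass as a list (adjusted p = 0.23). Of those 20 targets, 8 were higher and 2 lower in the former by either adjustment. Interferon genes, 12 of 23 lower and 1 higher, metallothioneins, 4 of 5 lower, NF-kB and chemokine genes, 10 of 18 lower and 4 higher, the amino acid stress response, 13 of 20 lower and 3 higher, and replication genes, 13 of 25 lower and 2 higher, passed at adjusted p = 0.000966, 0.00174, 0.0081, 0.00758 and 0.00758. With an estimated correlation they had adjusted p = 0.101, 0.101, 0.0748, 0.229 and 0.158, and adjusted over the list alone only the replication count changed, to 14 lower. Without DOX the correlation was 0.262 ± 0.025, where simulated unchanged groups sharing the untreated scramble arrays gave 0.501, with a covariance of 0.0769 against 0.0058 simulated. There 1396 genes were higher and 838 lower in both, with 927.86 and 458.08 expected, 928 of the 3162 genes called in both went opposite ways, and 8312 genes differed directly between arrays of different clusters.

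In arrays labelled si-PSTAR, DOX lowered mitotic genes and raised chemokine genes. Of 29 genes of G2/M and mitosis, 21 fell and 1 rose by either adjustment (camera adjusted p = 4.25e-26), with the kinesin KIF20A 3.25-fold, CENPE 2.82-fold, PLK1 2.55-fold and AURKA 2.52-fold lower. The second CENPE probe differed by -0.93. NF-kB and chemokine genes rose, 9 of 18 higher and 0 lower (11 and 0 adjusted over the list alone, adjusted p = 5.14e-09). The cytokine genes IL6 and CXCL8 were 8.01-fold and 7.14-fold higher, and CXCL2, RELB and CXCL10 2.47-fold, 2.15-fold and 2.14-fold higher. A second CXCL8 probe changed by 1.44. Interferon response genes rose, 9 of 23 (11 higher and 1 lower adjusted over the list alone, adjusted p = 4.6e-05), IRF1 2.85-fold and IFIT3 2.06-fold, although other IFIT3 probes differed by -0.12 and 0.60. Replication genes rose, 12 of 25 (16 adjusted over the list alone, adjusted p = 3.21e-07), E2F2 2.08-fold. Histone genes fell, 7 of 15 (9 adjusted over the list alone, adjusted p = 3.37e-07), with H2BC21 2.66-fold lower, as did 4 of 5 metallothionein genes (5 adjusted over the list alone, adjusted p = 4.82e-06). Of 26 ribosome biogenesis genes, 8 fell (10 lower and 3 higher adjusted over the list alone, adjusted p = 0.0123).

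The p53 targets of arrest, repair and feedback rose there, 5 of 20 higher and 1 lower by either adjustment (adjusted p = 0.027, 0.0427 with an estimated correlation). CDKN1A rose by 0.76, PPM1D by 0.87 and SESN2 by 0.56, ZMAT3 changed by -1.01, and the second CDKN1A probe differed by 0.02. Without untreated si-PSTAR replicate 3 the adjusted p of this list was 0.0852. The cell death targets did not pass (adjusted p = 0.317), with 2 higher and 0 lower by either adjustment. MDM2 differed by -0.04 (adjusted p = 0.79), HNRNPK by -0.12 (adjusted p = 0.463) and MYC by -0.38 (adjusted p = 0.0065), with 0.18 on the second MYC probe. DTL and TCIM were 2.12-fold and 2.04-fold higher, and PIF1, TNFAIP8L1, PIMREG, KIF14 and FAM83D 3.23-fold, 2.84-fold, 2.70-fold, 2.48-fold and 2.47-fold lower, and the second PIF1 probe differed by -0.11. In all, 2233 genes changed, 1273 higher and 960 lower, 31 of them at least 2-fold. The count was 884 in a fit of these 6 arrays alone and 1378 without DOX-treated si-PSTAR replicate 2.

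In scramble arrays, DOX went with higher IL6, 11.1-fold, GDF15, 5.07-fold, DDIT3, 3.51-fold, PLAAT4, 3.27-fold, and CDKN1A, 3.11-fold, the last differing by 1.05 on its second probe. SMC1A, HES2, CXCL8, JUN and TAP1 were 3.07-fold, 3.05-fold, 3.01-fold, 2.98-fold and 2.94-fold higher, and the second HES2 and CXCL8 probes differed by 0.87 and 0.52 log2 units, against 1.61 and 1.59 on the first. This comparison crosses the clusters of arrays, and its largest falls were those of RPL23, RPL23AP87, PTGES3, RPL23AP64 and HSPA1A, 43.8-fold, 37.5-fold, 31.3-fold, 25.7-fold and 24.8-fold lower, then AMY1A, ECT2 and RPS28 at 17.8-fold, 17.5-fold and 15.8-fold. KPNA2 changed by -4.09, and PTMA went from 10.11 to a dim level of 5.67. RPL23, PTGES3 and HSPA1A were also 31.3-fold, 24.7-fold and 22.7-fold lower in untreated arrays labelled si-PSTAR, which had no DOX. A second AMY1A probe changed by 0.12. MYC differed by -0.06 on one probe and by -4.60 on the other, and the first had -0.27 after cyclic loess (adjusted p = 0.0193).

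The counts of this paragraph were the same adjusted over the list alone. Mitotic genes fell with DOX in scramble, 18 of 29 (camera adjusted p = 5.42e-09). By the list test cholesterol synthesis genes also fell (adjusted p = 0.00798). Of 17, 6 were lower and 5 higher, with a median of 0.00 and a mean of -0.59. Ribosomal protein genes passed downward as well, 9 lower and 4 higher of 25 (adjusted p = 0.00123). Their median was -0.10 and their mean -0.54. For the same list, untreated arrays labelled si-PSTAR against untreated scramble gave a median of -0.0048 and a mean of -0.47 (adjusted p = 0.0582). Interferon response genes rose, 20 of 23 (adjusted p = 0.00166, and adjusted p = 0.0915 with an estimated correlation), and histone genes fell, 8 lower and 2 higher of 15 (adjusted p = 0.00798, and adjusted p = 0.0554 with an estimated correlation). Of the p53 targets of arrest, repair and feedback, 12 of 20 rose and 6 fell without passing (adjusted p = 0.704). Their median was 0.48 and their mean 0.29, while the median of all genes tested was 0.24. Of the cell death targets 10 of 17 rose and 4 fell, with a median of 0.33 and a mean of -0.11 (adjusted p = 0.952). MDM2 rose by 0.38 and HNRNPK differed by 0.23 (adjusted p = 0.0571), with -0.045 after cyclic loess and adjusted p = 0.0448 without untreated scramble replicate 2. In all, 8135 genes changed, 6278 higher and 1857 lower. The share that was higher was 77.2% as deposited and 51.1% after cyclic loess, which moved the median change from 0.24 to 0.05.

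In arrays labelled si-hnRNP K, also across the clusters, DOX went with higher IL6, by 2.38 on the log2 scale, and CDKN1A, 2.93-fold, the second CDKN1A probe differing by 0.28. SNORA12, FBXO32, FOXQ1, SNORD46, GALR2, EVA1A, IRF1 and SERTAD4-AS1 were 2.77-fold, 2.49-fold, 2.47-fold, 2.41-fold, 2.41-fold, 2.40-fold, 2.36-fold and 2.30-fold higher, and other probes of FBXO32 and EVA1A differed by 0.67 and by 0.62 and 0.73. RPL23, PTGES3, RPL23AP87, PTMA, RPL23AP64, HSPA1A, PERP, RPS28, AMY1A and FTH1P3 changed by between -4.74 and -3.59, and the second AMY1A probe differed by -0.15. List counts were the same adjusted over the list alone. Mitotic genes fell, 15 of 29 with 1 higher (adjusted p = 6.61e-07). Ribosomal protein genes passed downward, 9 lower and 6 higher of 25 (adjusted p = 0.00144), with a median of -0.06 and a mean of -0.44. Cholesterol synthesis, with a median of 0.02 and a mean of -0.41, and interferon, with 17 of 23 higher, passed at adjusted p = 0.0432 and 0.0498, and had adjusted p = 0.0864 and 0.348 with an estimated correlation. Neither p53 list passed (adjusted p = 0.843 for arrest, repair and feedback, with 10 higher and 6 lower, and 0.516 for cell death, with 8 higher and 3 lower). The medians of these lists were 0.25 and 0.23, while the test pointed down for both. MDM2, MYC and HNRNPK differed by -0.07, -0.11 and -0.19 (adjusted p = 0.556, 0.321 and 0.126), and the second MYC probe by -3.63. After cyclic loess MYC and HNRNPK had -0.30 and -0.43 (adjusted p = 0.011 and 0.00191). In all, 7335 genes changed, 77.5% of them higher, and after cyclic loess 4594 changed, 49.8% of them higher.

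Untreated arrays labelled si-PSTAR, set against untreated scramble across the clusters, had lower p53 targets of arrest, repair and feedback, 16 of 20 lower and 4 higher by either adjustment (camera adjusted p = 2.17e-05). DDB2 fell to a dim level of 5.58. PPM1D changed by -2.17, CCNG1 by -2.11 and CDKN1A by -1.63, and the second CDKN1A probe by 0.57. Cell death targets did not pass (adjusted p = 0.0934, 9 lower and 6 higher, or 10 and 6 adjusted over the list alone). Cholesterol synthesis genes fell, 10 of 17 with 3 higher (adjusted p = 0.00159), and amino acid stress genes rose, 16 of 20 with 2 lower (adjusted p = 0.00513, and adjusted p = 0.264 with an estimated correlation). SOD2 was 7.39-fold higher, and differed by 3.53 on its second probe. SMDT1, RN7SK, SNORD13, CALML4, SNORD3C, SNORD3A, KMT5B, VAMP1 and C1S were between 6.65-fold and 4.74-fold higher, the second RN7SK probe differed by 0.06 and other CALML4 probes by 0.96 and 1.35. Beside the RPL23 group named above, AMY1A, ECT2 and YAP1 changed by -4.94, -4.02 and -4.00, NACA4P stood at a dim level of 5.43 against 9.30, and the second AMY1A probe differed by 0.15. MDM2 rose by 0.36, with 0.21 after cyclic loess (adjusted p = 0.0538), and MYC rose by 0.79 on one probe and differed by -3.69 on the other. In all, 8269 genes changed, 65.9% of them higher as deposited and 45.5% after cyclic loess.

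The interactions asked whether the DOX response differed between arrays labelled with a targeting siRNA and scramble arrays. Of the 4 groups in the si-PSTAR interaction, untreated scramble alone lay in the smaller cluster, so the difference between clusters does not cancel there. Both untreated groups of the si-hnRNP K interaction lay in it. The correlation between the 2 brightest probes was 0.193 for the si-PSTAR interaction and 0.288 for the si-hnRNP K interaction. The SD of these interactions was 0.87 for si-PSTAR and 0.25 for si-hnRNP K, so the 2 correlations are not directly comparable. Where both probes were called, 297 of 416 genes had the same sign for si-PSTAR and 5 of 5 for si-hnRNP K. For si-hnRNP K, 396 genes differed, 256 higher and 140 lower as deposited. GDF15, RNU5A-1, SNORD43, HES2 and CXCL8 had interactions of -2.07, -1.82, -1.63, -1.29 and -1.10. ACSL4, CPOX, MSMO1, SNORD46 and MEX3C had interactions of 1.40, 1.40, 1.27, 1.16 and 1.11, the second ACSL4 probe one of -0.10 and other MSMO1 probes -0.022 and 0.62. The second CXCL8 and HES2 probes had -0.21 and -0.80. RNU5A-1 and SNORD43 were dim in DOX-treated scramble arrays, at 5.61 and 5.66, and HES2 in untreated arrays labelled si-hnRNP K, at 5.65. The sizes and ranks of the interactions of RNU5A-1, SNORD43 and HES2 therefore rest partly on dim levels. The count was 205 without untreated si-hnRNP K replicate 1, 219 and 231 without untreated scramble replicates 1 and 2, 247 without DOX-treated scramble replicate 1 and 243 without DOX-treated si-hnRNP K replicate 3. It was 661 in a fit of the compared arrays alone and 798 with array weights. The higher share of calls was 64.6% as deposited and 77.7% after cyclic loess. The p53 targets of arrest, repair and feedback did not pass (adjusted p = 0.0545), with 2 higher and 4 lower, or 3 and 8 adjusted over the list alone. That list passed without untreated scramble replicate 2 (0.0474), DOX-treated scramble replicate 2 (0.0275), untreated si-hnRNP K replicate 2 (0.0358) or DOX-treated si-hnRNP K replicate 2 or 3 (0.0335 and 0.0421). Of the cell death targets, 3 of 17 were lower (7 lower and 1 higher adjusted over the list alone, adjusted p = 0.0268, and adjusted p = 0.0979 with an estimated correlation), and the adjusted p was 0.099 without DOX-treated scramble replicate 3. For si-PSTAR, 6600 genes differed, 26.6% of them higher as deposited and 56.5% after cyclic loess. RPL23, RPL23AP87, RPL23AP64, PTGES3 and HSPA1A led the positive values at 5.71, 5.36, 4.89, 4.85 and 4.56, and GDF15, GSN, CCN1, RN7SK and IKBIP the negative ones at -1.83, -1.60, -1.43, -1.42 and -1.42. The second RN7SK probe had an interaction of 1.79, and other IKBIP probes differed by between -0.99 and 1.22. After cyclic loess 4078 genes differed. Neither p53 list passed there (adjusted p = 0.99 for arrest, repair and feedback, with 5 higher and 13 lower, or 6 and 13 adjusted over the list alone, and 0.886 for cell death, with 5 higher and 8 lower by either adjustment, a median of -0.29 and a mean of 0.21).

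The size of the DOX response was compared through genes called in the arm not compared. Its slope on the scramble response was 0.765 ± 0.032 (jackknife SE) in arrays labelled si-hnRNP K over 2233 genes. In arrays labelled si-PSTAR it was 0.00 ± 0.03 over 7335 genes. The scramble and si-hnRNP K responses both cross the clusters and the si-PSTAR response does not, so the slopes hold the difference between clusters as well as the drug.

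Most genes of secreted liver proteins were dim in cells labelled HepG2. Of 28 genes of secreted liver proteins with a probe, 22 lay below the median of all probes over the 18 arrays. AFP, which encodes alpha-fetoprotein, stood at 5.56 ± 0.15 log2 units (SD over 18 arrays), APOA1 at 5.49 ± 0.07 and APOB at 5.51 ± 0.09, and ALB, which encodes albumin, at 7.41 ± 0.92. CPS1 and ASS1, enzymes of the urea cycle, were bright at 13.63 and 11.47. Of 18 hepatocyte transcription factor and metabolism genes, 10 lay below the median and 5 above the 75th percentile of all probes. Of 16 housekeeping genes, 0 lay below the median. Of the 22 lists, 15 passed the list test in at least 1 of the 9 comparisons. The 7 that passed in none were hepatocyte secreted proteins, hepatocyte transcription factors and metabolism, hnRNP and related RNA-binding proteins, oxidative stress and xenobiotic genes, hypoxia and glycolysis, markers of other cell types and housekeeping genes.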

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

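The tests of the HNRNPK labels, of the liver genes and of the possibility that untreated si-PSTAR arrays had received drug were chosen after the result was seen, as were 3 of the 5 correlations of probe differences. The remaining correlations were set before their values were seen, but after the clusters of arrays were.

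The DOX response differed between arrays labelled si-PSTAR and scramble for 6600 genes and between those labelled si-hnRNP K and scramble for 396, by the interaction test of the difference itself. Untreated scramble is the one group of the si-PSTAR interaction in the smaller cluster of arrays, so its values hold the difference between clusters as well, and the 2 brightest probes of a gene correlated at 0.193 in it. Where the first of them differed by over 2-fold, its median size was 1.31 and that of the second probe in the same direction 0.18. For si-PSTAR the interactions were 5.71 for RPL23, 5.36 for RPL23AP87, 4.89 for RPL23AP64, 4.85 for PTGES3 and 4.56 for HSPA1A. They were -1.83 for GDF15, -1.60 for GSN, -1.43 for CCN1, -1.42 for RN7SK and -1.42 for IKBIP. For si-hnRNP K they were 1.40 for ACSL4, 1.40 for CPOX, 1.27 for MSMO1, 1.16 for SNORD46 and 1.11 for MEX3C, and -2.07 for GDF15, -1.82 for RNU5A-1, -1.63 for SNORD43, -1.29 for HES2 and -1.10 for CXCL8. Those of RNU5A-1, SNORD43 and HES2 rest partly on dim levels. In data outside the gene tests, 2348 of 5226 probes without a gene name had an interaction for si-PSTAR and 293 for si-hnRNP K.

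Among gene lists, ribosomal proteins had an interaction for si-PSTAR, 8 of 25 higher and 5 lower by either adjustment (adjusted p = 0.0261, and adjusted p = 0.252 with an estimated correlation), with a median of 0.05 and RPL14 at 4.34. After cyclic loess 0 lists passed for the si-PSTAR interaction. For si-hnRNP K, immediate early genes had negative interactions, 5 of 21 (7 adjusted over the list alone, adjusted p = 2.13e-06), KLF6 at -0.89. Mitotic genes had positive interactions, 5 of 29 (9 adjusted over the list alone, adjusted p = 2.59e-05), CDK1 at 0.96. Interferon genes had negative ones, 4 of 23 (6 adjusted over the list alone, adjusted p = 0.000189, and adjusted p = 0.0562 with an estimated correlation), as had NF-kB and chemokine genes, 4 of 18 (6 adjusted over the list alone, adjusted p = 0.00162), NFKB2 at -0.66. Cholesterol synthesis genes had positive ones, 2 of 17 (4 adjusted over the list alone, adjusted p = 0.0206, and adjusted p = 0.0558 with an estimated correlation). The cell death targets of p53 passed at an adjusted p of 0.0268, with an adjusted p of 0.0979 with an estimated correlation and of 0.099 without DOX-treated scramble replicate 3.

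Each of the 7 two-group comparisons allowed 10 splits of its 6 arrays, too few for a share under 0.05. The real split, 1 of the 10, called 8135 genes for DOX in scramble, 2233 for DOX in si-PSTAR, 7335 for DOX in si-hnRNP K, 8269 and 5618 for si-PSTAR without and with DOX, and 4153 and 4960 for si-hnRNP K without and with DOX. The highest of the other splits called 0 in each. Those splits mix arrays of both groups under each label, which widens the spread within a label, so the counts of 0 do not measure chance. For the si-PSTAR interaction, 2 of 100 splits gave as many genes as the real 6600, and the highest other gave 8114. For the si-hnRNP K interaction, 13 of 100 gave as many as the real 396 and the highest other gave 5931. Each split that gave as many kept or wholly exchanged the labels within 1 treatment, 2 of 16 and 13 of 18 such splits, and the highest in both cases exchanged the siRNA labels in 1 treatment only, which carries the differences between siRNA labels into the interaction: a structure of the samples. The other splits mix groups that differ strongly. Neither kind stands for samples without an interaction, and the counts depend on which 100 splits were drawn, so whether chance can be excluded stays open for both interactions.

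HNRNPK was low in arrays labelled si-PSTAR and near scramble in those labelled si-hnRNP K. Probes that cannot register a fall were argued against by the change of -3.63 in DOX-treated arrays labelled si-PSTAR. Exchanged labels of the si-PSTAR and si-hnRNP K groups, and an si-PSTAR that lowered HNRNPK beside an hnRNP K siRNA that did not, predict the same HNRNPK values, which were -0.59 with DOX and -0.17 without DOX in arrays labelled si-hnRNP K. Both may account for the pattern and cannot be told apart without a probe for PSTAR.

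The 6 untreated scramble and untreated si-hnRNP K arrays stood apart from the other 12. A probe-level difference between the sets of arrays may account for it: differences between probes of a gene correlated at 0.914 (95% bootstrap interval 0.895 to 0.929, across 1169 genes) between comparisons with no shared array. Between DOX in si-hnRNP K and DOX in si-PSTAR the correlation was -0.361 (interval -0.428 to -0.299). That argued against a drug effect on the measured part of transcripts that is alike in both siRNA arms. It cannot exclude a change that untreated si-PSTAR arrays already held, because DOX in si-PSTAR does not cross the sets. Such a change could also give the 0.914. The same doxorubicin treatment of untreated si-PSTAR arrays was argued against by the 17.9% of genes called between treated and untreated ones. A fit of those 6 arrays alone, however, called 884 of 12483, short of the 10% set for excluding it. Lists fixed beforehand also argued against the same treatment, for their genes. From untreated to treated si-PSTAR arrays, 21 of 29 mitotic genes fell and 1 rose (camera adjusted p = 4.25e-26, and 3.27e-06 with an estimated correlation). Of 18 NF-kB and chemokine genes, 9 rose and 0 fell (camera adjusted p = 5.14e-09). The probe differences of si-PSTAR with DOX correlated at -0.154 (interval -0.219 to -0.0888) with those of DOX in si-hnRNP K and at 0.0775 (-0.0103 to 0.164, which spans 0) with those of si-PSTAR without DOX, and the latter correlated at -0.445 (-0.513 to -0.372) with those of si-hnRNP K with DOX. Real effects of siRNA and drug stay open inside the comparisons that cross the sets.

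Of the secreted liver protein genes, 78.6% lay below the median of the probes in cells labelled HepG2, and of the hepatocyte transcription factor and metabolism genes 55.6%. The share of housekeeping genes there, 0%, decides nothing about weak signal or degraded RNA, because 16 of 16 lay above the 75th percentile of the probes and would stay above the median with a weaker signal too. Cells that differ from the labelled line or have lost part of its liver programme may account for the former, and both explanations stay open because no arrays of known HepG2 cells were compared. Levels of different probes were not calibrated to amounts of RNA, so a dim probe alone does not show that its RNA was scarce.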

How the results depend on the processing

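The fit of only the 12 arrays that clustered together was chosen after the result was seen. It called 5105 genes for si-PSTAR with DOX, 4408 for si-hnRNP K with DOX and 1557 for DOX in si-PSTAR. The values come as deposited, so dim genes are limited by an unknown background correction. Offsets for linear values were not run because the values are already log2, and centring on the 75th percentile changed nothing because the arrays share that percentile. Causes were not tested except where the construction of a setting shows them. Without the filter each of 18 main results was labelled the same. Gene counts and correlations stayed within the limits set for them, and HNRNPK kept its direction and side of the threshold. Cyclic loess gave 4594 genes for DOX in si-hnRNP K with 7 lists past and HNRNPK at -0.43, 4078 genes for the si-PSTAR interaction with 0 lists, and an adjusted p of 0.0381 for the p53 arrest list in the si-hnRNP K interaction. HNRNPK for DOX in scramble was 0.23 and passed with the stricter filter, with only the compared arrays, with the trended prior and, at 0.23, with array weights. With the mean of all probes, HNRNPK was -0.26 for DOX in scramble, -0.28 for DOX in si-hnRNP K and -0.20 for si-hnRNP K without DOX. In the same setting MYC and HNRNPDL reversed to -1.45 and -0.88 for si-PSTAR without DOX, RPL13 to 0.10 for si-hnRNP K without DOX, and RN7SK and SNHG5 to 0.19 and 0.44 in the si-PSTAR interaction. Other HNRNPK probes gave -1.17 for DOX in scramble, -0.91 for DOX in si-hnRNP K, 0.43 for DOX in si-PSTAR, 0.10 for si-PSTAR with DOX, and -0.20, 0.027 and -0.11 for si-hnRNP K with DOX. Only the compared arrays gave 884 genes for DOX in si-PSTAR and 661 for the si-hnRNP K interaction, for which array weights gave 798.

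With an estimated correlation, 3 lists passed for DOX in scramble, 2 for DOX in si-hnRNP K, 3 for si-PSTAR with DOX, 0 for the si-PSTAR interaction and 3 for the si-hnRNP K interaction, where the cell death list had an adjusted p of 0.0979. Fry, which compares no list with other genes, passed 19 lists for DOX in scramble, 13 for DOX in si-PSTAR, 18 for DOX in si-hnRNP K, 17 and 18 for si-PSTAR without and with DOX, 17 and 17 for si-hnRNP K, and 9 and 10 for the interactions. For the p53 arrest list fry gave 1.25e-09 for DOX in scramble, 4.21e-06 upward for DOX in si-hnRNP K where camera pointed down, and 0.000113 and 0.000189 for the si-PSTAR and si-hnRNP K interactions. For the cell death list it gave 0.0268 for DOX in si-PSTAR, 0.000294 for DOX in si-hnRNP K, 2.5e-08 and 4.43e-07 for si-PSTAR without and with DOX, and 1.45e-05 for si-hnRNP K with DOX. Fry reversed direction, for DOX in scramble, for markers of the epithelial to mesenchymal transition (0.00951), hepatocyte transcription factors and metabolism (0.00447), long noncoding RNA genes (0.000485) and markers of other cell types (0.0179). It did so for DOX in si-hnRNP K for hepatocyte transcription factors (0.00397), immediate early genes (0.0182) and long noncoding RNA genes (0.00159), for NF-kB genes in si-PSTAR without DOX (1.61e-06), and for hepatocyte transcription factors in the si-PSTAR interaction (0.033).

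Leaving out 1 array at a time gave 1378 to 2289 genes for DOX in si-PSTAR, the lowest without DOX-treated si-PSTAR replicate 2, and 205 to 441 for the si-hnRNP K interaction, the lowest without untreated si-hnRNP K replicate 1. HNRNPK for DOX in scramble ranged from 0.19 to 0.28, and lists past for DOX in si-hnRNP K from 2, without DOX-treated si-hnRNP K replicate 3, to 5. The adjusted p of the arrest list ranged from 0.0239 to 0.0852 for DOX in si-PSTAR and from 0.0275 to 0.143 in the si-hnRNP K interaction. That of the cell death list ranged from 0.0432 to 0.158 for si-hnRNP K with DOX and from 0.00545 to 0.099 in the interaction. The correlation between the differences of the si-PSTAR and si-hnRNP K labelled arrays from scramble with DOX ranged from 0.439 to 0.464. With the replicate block each of 43 main results was labelled the same. HNRNPK and the p53 lists kept their side of the threshold. Gene and list counts stayed within the limits set for them, with 5654 genes for si-PSTAR with DOX and 406 for the si-hnRNP K interaction. Same-numbered arrays had a mean correlation of deviations of 0.0054, 6 of 45 pairs exceeded 0.1, and 5 of 18 arrays correlated best with their own number, so the numbers do not pair the arrays.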

Other observations

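Genes outside the lists that passed also differed. ALB, which encodes albumin, was 4.37-fold and 3.58-fold higher in arrays labelled si-hnRNP K without and with DOX than in scramble, while its list of secreted liver proteins did not pass (adjusted p = 0.223 and 0.192). GCLM, a subunit of the enzyme that starts glutathione synthesis, rose by 1.85 and 2.06 there, while AKR1C2 changed by -1.17 and -1.07, AKR1C3 by -1.36 and -1.12 and the transporter gene ABCC3 by -1.25 and -1.61. In DOX-treated arrays labelled si-PSTAR, GCLM rose by 0.91 and AKR1C2 by 1.49, and HMOX1 changed by -0.80. The list of oxidative stress and xenobiotic genes did not pass in these comparisons (adjusted p = 0.0813 and 0.186 for si-hnRNP K without and with DOX, and 0.152 for si-PSTAR with DOX).

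HNRNPU, which encodes another hnRNP, changed by -0.89 and -0.79 in arrays labelled si-hnRNP K without and with DOX and rose by 0.88 in DOX-treated arrays labelled si-PSTAR. With DOX it differed by -1.67 between arrays labelled si-hnRNP K and those labelled si-PSTAR (limma adjusted p = 1.87e-13). PFKFB3, a regulator of glycolysis, rose by 1.09 and 0.80 in arrays labelled si-hnRNP K, and ANKRD37 changed by -1.07 in DOX-treated arrays labelled si-PSTAR. Among markers of other cell types, DCN changed by -1.58 and -1.31 in arrays labelled si-hnRNP K and rose by 1.20 in DOX-treated arrays labelled si-PSTAR, and CDH5 changed by -1.82 in the latter.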
